A study of Mus musculus and Rattus norvegicus with 14 samples.

How the data were processed

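Messenger RNA was measured in 12 mouse heart libraries, in 4 groups of 3, and in 2 libraries of primary rat cells. Groups were taken from the sample titles for the mouse and from the sample descriptions for the rat. Per the labels' protocols, RNA was extracted with trizol and messenger RNA was captured with poly-T beads. Those protocols describe both a NEB library and a strand-specific dUTP library without saying which was sequenced. The submitters' processing notes name fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 without roles, and the builds mm10 and Rnor_6.0, which were assigned here by organism. The annotation release and the strand setting used in counting are not given in the sources used here, so genes that overlap another gene are uncertain. Genes with near-identical copies, and mitochondrial genes with copies in the nuclear genome, are uncertain as well, because the handling of reads with several matches is not stated.

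The authors deposited FPKM values (reads divided by gene length and by a measure of library size) for 54532 mouse and 33600 rat genes, with gene lengths and coordinates. In each library the product of FPKM and gene length was a whole multiple of a single step for 100.0% of values (tolerance 0.02 of a read), so whole reads were recovered. The mouse libraries held 13085370 to 16698987 recovered reads, and 1 read in a gene of 1 kilobase was worth 0.0566 to 0.0805 FPKM. The rat libraries held 13262387 (2D) and 11910160 (3D) reads. The divisor behind the deposited FPKM was 0.828 to 1.164 times the recovered sum in the mouse libraries and 1.016 and 0.984 times in the rat libraries, a scaling that no label states. Among rat genes, 717 had no gene name and were not named here.

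Mouse FPKM of each library were divided by a median-of-ratios factor over the 10422 genes with at least 1 FPKM in every library; these values are called scaled FPKM. The factor was computed because mitochondrial and contractile transcripts can take a variable share of heart RNA. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested (13000). Values were analysed as log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), with all 12 libraries in one fit so that the groups share an estimate of the spread (10.9 degrees of freedom in all). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a mouse gene in the text comes from limma unless limma-voom is named. Fold changes and their standard errors are on the log2(scaled FPKM + 1) scale, which understates the change of low genes, so that a fold differs from the ratio of the printed means. Group values are means ± SD of scaled FPKM.

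The 32 gene lists (pathways and markers of cell types a heart piece or the co-culture could hold) were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of each comparison, for lists of at least 4 tested members. Camera with an estimated correlation is given beside each list that passed, and fry was run as a further check; fry asks whether the members move one way and does not compare them with other genes. For shared Model libraries, treated groups equal to Model were simulated 100 times from resampled residuals. The position of a library on a list is its projection on the Model minus Sham difference over all tested members, with the Sham mean at 0 and the Model mean at 100.

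Rat values were scaled by the median ratio over 12109 genes with at least 1 FPKM in both libraries. Genes with at least 1 FPKM in either library were compared (13405) as log2 ratios of scaled FPKM + 1 without a test, and list medians were placed among 10000 random lists matched on expression in 10 bins. Printed read ratios are ratios of recovered reads adjusted for depth, with exact 95% binomial intervals, and 3 reads served as the floor where a library held 0. The 3D culture differs from the 2D cells in more than 1 respect by its label, and the parts cannot be separated here.

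The tests, filters, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named genes were the 10 largest called changes per direction among named protein-coding genes with a mean of at least 2 scaled FPKM in 1 of both groups and no overlap of libraries, up to 4 called members of each list by smallest p, up to 2 uncalled members of described lists as values, and 10 genes fixed in advance (Col1a1, Col3a1, Fn1, Postn, Acta2, Tgfb1, Nppa, Nppb, Myh7 and Myh6). Where no gene passed, the 5 per direction with the smallest unadjusted p were named. For each compound against Sham only the 10 fixed genes and counts were given. In the rat the 12 highest and 12 lowest ratios among genes of at least 10 FPKM were eligible. Not every eligible gene is printed.

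Alternatives were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, only the 2 groups compared, the replicate number as a block, a limit of 1 on the log2 fold change, limma-voom on recovered reads, and leaving out each library. Neither scaling alternative moved the median log2 change of all genes by more than 0.1. The mouse test was tested for Model against Sham on simulated data made from the mean spread within the 4 mouse groups, with 100 genes planted per fold in 5 runs of 13000 genes. It recovered 53.6% of 2-fold and 84% of 4-fold changes with 4.1% false among the calls, and called at most 1 gene with no effect planted. These genes were drawn independently of each other, so this simulation leaves out deviations that genes of a library share. Groups simulated as equal to Model from resampled residuals, which keep them, gave a mean of 0.15 calls for LQ-40 and 12.45 for SQ-3 against Model. The highest counts there were 10 and 1194, each from a single simulation that made up most of the mean. The placing of rat lists was tested on 200 simulated lists of 20 genes among 13405, of which 7.0% without a shift and 100.0% with a planted 2-fold shift fell outside the central 95%. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.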

Results

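Messenger RNA was measured by sequencing in 12 mouse heart libraries and 2 libraries of primary rat heart cells. The mouse libraries formed 4 groups of 3, labelled Sham, Model, LQ-40 and SQ-3. LQ-40 and SQ-3 are code names of 2 compounds whose effects on myocardial fibrosis the study set out to compare, with their structural similarity in view. The labels used here give no dose, treatment time, model procedure or time of day at collection, and do not say that the LQ-40 and SQ-3 hearts had undergone the model procedure. They also do not say that the libraries of a group came from separate animals, so p-values here measure only the spread between these samples, which may be technical. The rat libraries came from cardiomyocytes, cardiac fibroblasts and bone-marrow derived macrophages, grown either as a 3D co-culture or as 2D cells of the 3 types mixed 1:1:1.

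The mouse libraries held 13085370 to 16698987 reads assigned to genes, and 13000 genes were tested. The mitochondrial genome took 19.9 ± 4.7% of reads in Sham, 13.4 ± 2.4% in Model, 15.9 ± 5.1% in LQ-40 and 17.0 ± 2.7% in SQ-3 hearts (SD, n = 3 each). The first principal component held 53.4% of the variance. Sham libraries lay between -52.5 and -43.7 on it and Model libraries between 26.3 and 36.2. The 3 LQ-40 libraries lay at -20.6, 16.0 and 34.3, and the SQ-3 libraries between 0.2 and 17.7.

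The first comparison set Model hearts against Sham hearts. Structural genes of the extracellular matrix rose in Model hearts. Col1a1, the main chain of fibrillar type I collagen (chromosome 11, 94936224 to 94953042, mm10), averaged 877 ± 126 scaled FPKM in Model and 79.3 ± 42.2 in Sham hearts (SD, n = 3 each), 12.4-fold higher (log2 3.63, SE 0.57, limma adjusted p = 0.00142). Col3a1, which encodes type III collagen (chromosome 1, 45311538 to 45349706), rose 10.4-fold (1119 ± 39.2 against 114.7 ± 48.2, adjusted p = 0.000879), and Fn1, which encodes fibronectin (chromosome 1, 71585520 to 71653200), rose 13.9-fold (155.0 ± 22.8 against 10.3 ± 2.46, adjusted p = 0.000214). Eln, the elastin gene, rose 19.2-fold (186.5 ± 7.80 against 8.96 ± 2.40, adjusted p = 2.86e-05). Comp, a cartilage matrix protein that binds collagen fibrils (chromosome 8, 70373558 to 70382066), had the largest fold change of the named genes, 90.1-fold (186.2 ± 74.4 against 0.947 ± 0.145, SE 0.96 on the log2 scale, adjusted p = 0.0011). Fmod, a proteoglycan of collagen fibrils, rose 36.2-fold (adjusted p = 0.00118). All 32 tested members of the list of collagens and structural matrix rose (32 adjusted over the list alone; median log2 change 2.83, camera adjusted p = 2.92e-16, adjusted p = 0.371 with an estimated correlation).

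Enzymes that process the matrix, and their inhibitors, also rose. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735), went from 2.90 ± 1.00 to 83.7 ± 14.4 scaled FPKM (22-fold, SE 0.75 on the log2 scale, adjusted p = 0.00206). Mmp14, a membrane-bound metalloproteinase, rose 7.40-fold (adjusted p = 0.000131), and Loxl1, which crosslinks elastin, rose 8.11-fold (adjusted p = 0.000214). Of 29 tested members of this list 21 rose and none fell (24 up and 1 down adjusted over the list alone; median 1.53, adjusted p = 5.36e-09, adjusted p = 0.371 with an estimated correlation). The Wnt pathway modulator Sfrp2 rose 40.8-fold (96.0 ± 13.2 against 1.48 ± 0.845, adjusted p = 0.000417).

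Fibroblast genes and genes of the TGF-beta pathway, a main inducer of matrix synthesis, followed the same direction. Postn, a matricellular protein of activated fibroblasts (chromosome 3, 54361109 to 54391037), rose 13.3-fold (183.6 ± 20.2 against 13.2 ± 4.06, adjusted p = 0.00137) and Thbs4 rose 26.8-fold (adjusted p = 0.000704). Pi16, a marker of resident adventitial fibroblasts, rose 4.74-fold (adjusted p = 0.00126). Among TGF-beta ligands, Tgfb3 rose 8.04-fold (60.2 ± 8.55 against 6.57 ± 0.534, adjusted p = 0.000224) and Tgfb1 rose 1.93-fold (13.2 ± 1.93 against 6.47 ± 1.83, adjusted p = 0.00302). In the list of activated fibroblast and myofibroblast genes 12 of 15 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 8.21e-06), 10 of 14 resident fibroblast genes rose (10 adjusted over the list alone; adjusted p = 1.97e-05), and 17 of 22 TGF-beta pathway genes rose (18 adjusted over the list alone; adjusted p = 2.65e-06). For each of these 3 lists the value was adjusted p = 0.371 with an estimated correlation. Acta2, the smooth muscle actin of myofibroblasts, averaged 167.7 ± 4.6 in Model and 123.4 ± 8.15 in Sham hearts and did not pass the test (log2 0.44, adjusted p = 0.0504). It passed in a fit of the 2 groups alone (adjusted p = 0.0149) with quantile normalization (0.00599), a mean of at least 5 FPKM (0.0465), a pseudocount of 0.1 (0.0484) and limma-voom (0.0443), within a range of 0.00599 to 0.135 over all alternatives.

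Genes of the contractile apparatus and of mitochondrial energy supply fell in Model hearts. Tnni3, cardiac troponin I (chromosome 7, 4518305 to 4524229), was 2.60-fold lower (695.8 ± 129.7 against 1806 ± 293, log2 -1.38, SE 0.29, adjusted p = 0.00562), and Ttn, which encodes titin, was 1.74-fold lower (adjusted p = 0.00702). Of 20 tested contractile genes 17 fell (20 adjusted over the list alone; median -1.04, adjusted p = 3.68e-08, adjusted p = 0.371 with an estimated correlation). Acadl, an enzyme of fatty acid oxidation, was 2.24-fold lower (adjusted p = 0.00298) and the mitochondrial carrier Ucp3 5.38-fold lower (1.51 ± 0.322 against 14.4 ± 8.77, adjusted p = 0.00495). In the fatty acid oxidation list 17 of 21 genes fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 1.15e-06, adjusted p = 0.456 with an estimated correlation). Ndufb5 and Ndufs1, subunits of respiratory complex I, were 2.37-fold and 2.34-fold lower (adjusted p = 0.00265 and 0.0037). Of 28 nuclear genes of oxidative phosphorylation 27 fell (28 adjusted over the list alone; median -1.12, adjusted p = 8.34e-12, adjusted p = 0.371 with an estimated correlation). Of 13 genes encoded in mitochondria 2 fell, mt-Nd3 (3.13-fold lower, adjusted p = 0.01) and mt-Co2 (2.61-fold lower, adjusted p = 0.022), with 2 adjusted over the list alone (list adjusted p = 0.00817, adjusted p = 0.585 with an estimated correlation). The mt-Co2 call was lost without Sham 2 (0.0513), Sham 3 (0.0707) or Model 1 (0.0869), with quantile normalization (0.225) and without a filter (0.189), within a range of 0.00729 to 0.225 over all alternatives.

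Myh6, the main myosin heavy chain of adult mouse ventricle, averaged 1624 ± 91.7 in Model and 3831 ± 541 in Sham hearts (2.34-fold lower, adjusted p = 0.0143). This call was lost with quantile normalization (adjusted p = 0.439) and without a filter (0.209), in a range of 0.00262 to 0.439 over all alternatives. Myh7, the fetal heavy chain, averaged 44.7 ± 11.2 and 53.8 ± 5.52 (log2 -0.29, adjusted p = 0.299). The natriuretic peptide gene Nppb rose 5.36-fold (702.4 ± 116.0 against 132.4 ± 37.1, adjusted p = 0.0126) and Nppa rose 6.48-fold (1813 ± 953 against 262.7 ± 72.5, adjusted p = 0.021). The Nppa call was lost without Sham 1 (adjusted p = 0.058), Sham 2 (0.0634) or Model 3 (0.0737) and without a filter (0.0584), in a range of 0.00184 to 0.0737 over all alternatives. Gdf15, a stress cytokine, rose 17.2-fold (21 ± 8.49 against 0.208 ± 0.0461, adjusted p = 0.000358), and Rcan1, a target of calcineurin signalling, rose 3.36-fold (adjusted p = 0.000435). Of 13 cardiac stress and fetal genes 6 rose (6 adjusted over the list alone; adjusted p = 0.00638, adjusted p = 0.541 with an estimated correlation).

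Every one of the 20 tested interferon response genes fell in Model hearts (20 adjusted over the list alone; median -2.62, adjusted p = 5.33e-18, adjusted p = 0.298 with an estimated correlation). Ifit1, an antiviral protein induced by type I interferon (chromosome 19, 34640871 to 34650009), averaged 3.34 ± 1.65 in Model and 61.7 ± 13.7 in Sham hearts (15.1-fold lower, log2 -3.91, SE 0.31, adjusted p = 4.45e-05). Isg15, a ubiquitin-like antiviral protein, was 11.3-fold lower (9.31 ± 3.52 against 110.7 ± 17.3, adjusted p = 0.000128), and Irf7, a transcription factor of the pathway, was 13.3-fold lower (adjusted p = 4.45e-05). Iigp1, an interferon-induced GTPase (chromosome 18, 60376029 to 60392627), was 24.6-fold lower (9.27 ± 4.31 against 241.9 ± 77.1, adjusted p = 2.86e-05). Igtp was 25.4-fold lower (adjusted p = 2.86e-05), a value that is uncertain because Igtp overlaps Irgm2 on the genome and the strand used in counting is not stated.

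Clock genes, protein folding genes and immediate early genes also differed. Dbp, a transcription factor driven by the circadian clock (chromosome 7, 45705088 to 45710203), averaged 4.14 ± 1.81 in Model and 40.2 ± 3.64 in Sham hearts (8.33-fold lower, log2 -3.06, SE 0.21, adjusted p = 2.86e-05). Tef and Per3 were 3.86-fold and 3.28-fold lower (adjusted p = 2.86e-05 for both). Arntl, the clock activator also called Bmal1 (chromosome 7, 113207465 to 113314126), rose 4.48-fold (4.62 ± 1.17 against 0.239 ± 0.113, adjusted p = 2.86e-05). Of 16 clock genes 4 rose and 9 fell (4 and 9 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.371 with an estimated correlation). Xbp1, a regulator of the unfolded protein response, rose 2.20-fold (44.0 ± 0.659 against 19.5 ± 1.20, adjusted p = 0.000207) and the chaperone Pdia4 rose 2.63-fold (adjusted p = 0.000885). In the protein folding stress list 9 of 17 genes rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00241, adjusted p = 0.281 with an estimated correlation). Of 15 immediate early genes, which respond within minutes to stimulation, 12 rose (13 adjusted over the list alone; adjusted p = 4.5e-06, adjusted p = 0.371 with an estimated correlation), among them Egr1 (4.29-fold, adjusted p = 0.00157) and Egr2 (4.82-fold, adjusted p = 0.000456).

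Markers of several other cell types moved as well. Cd14, a co-receptor for bacterial lipids on myeloid cells, rose 3.44-fold (40.2 ± 4.09 against 10.9 ± 0.34, adjusted p = 0.000512), Gpnmb 5.09-fold (adjusted p = 0.000689) and Csf1r, the receptor that keeps macrophages alive, 2.05-fold (adjusted p = 0.00126). Of 23 macrophage genes 13 rose and 1 fell (18 and 2 adjusted over the list alone; adjusted p = 0.000161, adjusted p = 0.541 with an estimated correlation). Of 7 mesothelial and epicardial genes 4 rose (5 adjusted over the list alone and 1 by limma-voom; adjusted p = 0.0184, adjusted p = 0.563 with an estimated correlation), a list that did not pass without Model 2 (median 1.32 in place of 1.96). The remaining lists did not pass. They were cytokines and chemokines (4 of 18 up, 1 down; list adjusted p = 0.272), with Cxcl9, an interferon-induced chemokine, 3.14-fold lower (adjusted p = 0.0032), endothelial genes (3 of 13 up, 2 down; 0.588), with Vwf 2.24-fold higher (0.00492), and smooth muscle and pericyte genes (4 of 10 up; 0.272), with Pdgfrb 1.87-fold higher (0.00153). Adipocyte genes (2 of 6 down; list adjusted p = 0.501), with Fabp4 2.19-fold lower (0.00797), and genes of hypoxia and glycolysis (7 of 26 up, 4 down; 0.977), with Pgam1 2.01-fold higher (0.000501) and Pdk1 1.53-fold lower (0.00773), also did not pass. Nor did xenobiotic and oxidative stress genes (2 of 13 up, 4 down; 0.788), with Cyp1b1 5.45-fold higher (0.000865), glucocorticoid-responsive genes (2 of 12 up; 0.552), with the cell cycle inhibitor Cdkn1a 2.86-fold higher (0.000973), cell cycle genes (2 of 20 up, 1 down; 0.0933), Schwann cell genes (1 of 4 up; 0.909) or sex-linked genes (1 of 4 down; 0.272). Median, mean and test differed in sign for endothelial (-0.14, 0.03, down), adipocyte (0.36, 0.02, down), Schwann cell (-0.17, 0.05, down) and neutrophil genes (-0.57, -0.12, up).

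No gene was called by limma among 5 neutrophil, 4 T and B lymphocyte, 6 erythroid and 7 MHC class II genes (list adjusted p = 0.991, 0.771, 0.12 and 0.284); limma-voom on recovered reads also called 0, and at an unadjusted p under 0.05 there were 1, 0, 2 and 0 genes. The atrial list had 3 tested members, of which 1 fell, and the skeletal muscle list 2, of which 1 rose, too few for a list test.

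Over all genes, 2718 rose and 2335 fell in Model hearts, 844 and 610 of them by at least 2-fold. With FPKM as deposited 2482 rose and 2604 fell, and with quantile normalization 2264 and 2411, so which direction held more genes depended on the scaling. The libraries of the groups did not overlap for 7221 genes, or 55.5%, where chance gives 10% for 3 against 3. Without Model 1 the count of 5053 calls became 3288. Among the lists with at least 4 tested members 16 passed with the preset correlation and 0 of camera's tests passed with an estimated one.

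**Figure D1:**
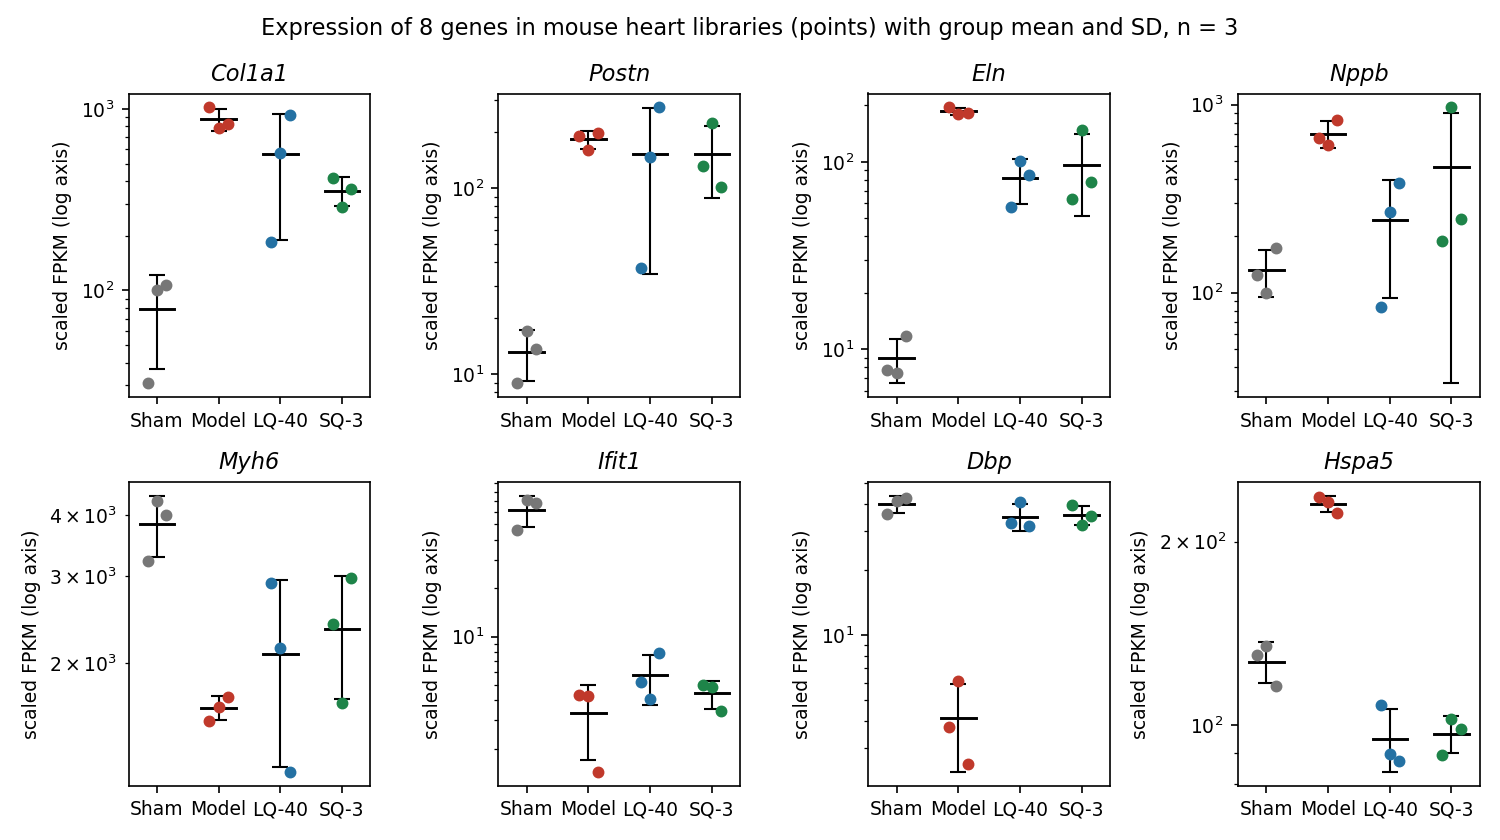
Scaled FPKM of 8 genes in the 12 mouse heart libraries on log axes, 1 panel per gene; points are libraries, bars the group mean and whiskers the SD (n = 3 per group). Dbp averaged 40.2 in Sham, 4.14 in Model, 35.1 in LQ-40 and 35.8 in SQ-3 hearts, whereas Col1a1 averaged 79.3, 877, 561 and 355.

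LQ-40 hearts were compared with Model hearts to describe the effect of the first compound. Clock genes differed in both directions. Dbp averaged 35.1 ± 5.05 in LQ-40 and 4.14 ± 1.81 in Model hearts (SD, n = 3 each), a 7.28-fold rise (log2 2.86, SE 0.21, limma adjusted p = 0.000189). Per3, a repressor within the clock, rose 3.69-fold (adjusted p = 0.000136) and Tef 3.67-fold (adjusted p = 0.000189). Arntl was 4.07-fold lower (0.362 ± 0.0714 against 4.62 ± 1.17, adjusted p = 0.000222), and the clock-controlled repressor Nfil3 3.17-fold lower (adjusted p = 0.00201). Of 16 clock genes 7 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p = 2.43e-05, adjusted p = 0.112 with an estimated correlation).

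The protein folding and immediate early lists were lower in LQ-40 hearts. Hspa5, the main chaperone of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), averaged 95.1 ± 11.2 against 230.7 ± 7.14 (2.42-fold lower, log2 -1.28, SE 0.13, adjusted p = 0.00144), and the heat shock protein Hsph1 was 2.08-fold lower (5.94 ± 0.0827 against 13.5 ± 0.945, adjusted p = 0.00524). In the protein folding stress list 5 of 17 genes fell (12 adjusted over the list alone; median -0.49, adjusted p = 4.3e-13, adjusted p = 0.0014 with an estimated correlation). Nr4a3, an orphan nuclear receptor induced by many stimuli, was 3.08-fold lower (adjusted p = 0.000289). Of 15 immediate early genes 3 fell (14 adjusted over the list alone; adjusted p = 2.01e-12, adjusted p = 0.241 with an estimated correlation), among them Nr4a1 (6.56-fold lower, adjusted p = 0.0345). The Nr4a1 call was lost without Model 2 (0.108), Model 3 (0.164), LQ-40 1 (0.109) or LQ-40 2 (0.0849), without a filter (0.0904) and in a fit of the 2 groups alone (0.161), in a range of 0.0244 to 0.164 over all alternatives. Cdkn1a, the only called gene of 12 glucocorticoid-responsive ones (2 adjusted over the list alone; list adjusted p = 0.298), was 3.38-fold lower (adjusted p = 0.00502), and the angiogenic factor Vegfa, the only called gene of 26 in the hypoxia and glycolysis list (3 adjusted over the list alone; list adjusted p = 0.0382, adjusted p = 0.48 with an estimated correlation), was 1.99-fold lower (22.7 ± 3.91 against 45.7 ± 2.47, adjusted p = 0.00572).

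Among cardiac stress and fetal genes 3 of 13 fell (5 adjusted over the list alone; adjusted p = 1.11e-05, adjusted p = 0.48 with an estimated correlation). Gdf15 was 7.41-fold lower (2.13 ± 1.70 against 21 ± 8.49, log2 -2.89, SE 0.47, adjusted p = 0.0217), a call lost without Model 1 (0.0976), Model 3 (0.108), LQ-40 1 (0.064) or LQ-40 2 (0.0709), without a filter (0.0659) and in a fit of the 2 groups alone (0.166), and ranging from 0.0118 to 0.166 over all alternatives. Rcan1 was 2.76-fold lower (adjusted p = 0.0102), a call lost without Model 3 (0.061) and in a fit of the 2 groups alone (0.165) and ranging from 0.00819 to 0.165. Nppa averaged 902.2 ± 713.4 in LQ-40 hearts (log2 against Model -1.25, adjusted p = 0.571), Nppb 244.3 ± 150.8 (-1.76, 0.284), Myh7 46.6 ± 8.09 (0.07, 0.915) and Myh6 2090.0 ± 855.4 (0.27, 0.778), none of which passed. The signs of the last 2 were not stable. Myh7 took -0.12 without Model 2 and -0.05 without LQ-40 3, and Myh6 -0.01 without LQ-40 1.

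Collagen genes lay between Sham and Model levels on average, with a wide spread, and did not pass singly. Col1a1 averaged 561 ± 370 scaled FPKM in LQ-40 hearts (log2 against Model -0.92, 95% interval -2.17 to 0.34, adjusted p = 0.565), Col3a1 822 ± 553 (-0.69, adjusted p = 0.598), Fn1 148.4 ± 88.4 (-0.27, 0.821) and Eln 81.5 ± 22.1 (-1.22, 0.112). Postn averaged 152.6 ± 118.1 (-0.67, 0.691), Acta2 117.7 ± 6.44 (-0.51, 0.224), Tgfb1 9.72 ± 1.56 (-0.41, 0.375) and Tgfb3 28.6 ± 13.5 (-1.17, 0.151). Without LQ-40 1 the sign turned for Fn1 (0.31) and Postn (0.13). By list, the collagens and structural matrix were lower (median -0.70, adjusted p = 4.2e-09, adjusted p = 0.48 with an estimated correlation), although limma called 0 of 32 members (0 adjusted over the list alone, 11 at an unadjusted p under 0.05, all lower, and 0 by limma-voom). Without LQ-40 1 this median shrank to -0.23, and the list still passed. The matrix-modifying list was lower (adjusted p = 5.45e-05, adjusted p = 0.553 with an estimated correlation), with 1 of 29 members called (1 up and 6 down adjusted over the list alone). This was Adamts4, a protease that cleaves proteoglycans, 3.58-fold lower (0.539 ± 0.675 against 4.21 ± 0.244, adjusted p = 0.00607). Lists of activated fibroblast genes (median -0.67, adjusted p = 0.000129, adjusted p = 0.48 with an estimated correlation) and of the TGF-beta pathway (median -0.42, adjusted p = 0.00161, adjusted p = 0.553 with an estimated correlation) were lower with 0 of 15 and 0 of 22 genes called by limma, 0 by limma-voom, 4 and 0 adjusted over the list alone, and 4 and 6 at an unadjusted p under 0.05 (for TGF-beta 1 higher and 5 lower). Without LQ-40 1 the matrix-modifying, activated fibroblast and TGF-beta lists did not pass (medians -0.09, -0.20 and -0.09).

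Interferon genes were higher than in Model hearts as a list (median 0.49, adjusted p = 3.49e-07, adjusted p = 0.48 with an estimated correlation), with 0 of 20 called by limma, 0 by limma-voom, 7 at an unadjusted p under 0.05 and 4 adjusted over the list alone. Iigp1, outside that list, rose 5.12-fold to 48.2 ± 6.68 (adjusted p = 0.00851), against 241.9 ± 77.1 in Sham hearts. Contractile genes (median 0.18, adjusted p = 0.0464, adjusted p = 0.72 with an estimated correlation), oxidative phosphorylation (0.24, adjusted p = 0.00198, adjusted p = 0.679 with an estimated correlation) and fatty acid oxidation (0.30, adjusted p = 0.0116, adjusted p = 0.679 with an estimated correlation) were higher as lists, with 0 of 20, 0 of 28 and 0 of 21 genes called by limma, 0 by limma-voom and 0, 0 and 1 at an unadjusted p under 0.05. This rise rested on LQ-40 1, without which the 3 medians were -0.06, -0.06 and -0.05 and none passed. Ndufb5, for example, averaged 42.3 ± 15.5 (log2 against Model 0.36, adjusted p = 0.564). The macrophage list did not pass (adjusted p = 0.314), and Cd14 averaged 26 ± 8.85 (log2 -0.66, adjusted p = 0.259). Further lists passed with the preset correlation only, higher for neutrophil (median 0.68, adjusted p = 0.0116), T and B lymphocyte (0.72, 0.0382), MHC class II (0.72, 0.0171), erythroid (0.57, 0.0372), adipocyte (0.65, 0.0372) and mitochondrially encoded genes (0.28, 0.0278) and lower for smooth muscle and pericyte genes (-0.18, 0.0494), with adjusted p = 0.48 to 0.676 with an estimated correlation. Limma and limma-voom called 0 genes in each, against 2, 1, 1, 0, 0, 1 and 2 at an unadjusted p under 0.05, and each of these 7 lists did not pass without 1 or more of the 6 libraries. The xenobiotic list did not pass either (adjusted p = 0.611; median -0.06, mean 0.11, test direction up).

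In all, 24 genes rose and 63 fell in LQ-40 against Model hearts, and 18.1% of genes had groups that did not overlap, where chance gives 10%. The count of 87 became 55 without Model 1, 31 without Model 3, 50 without LQ-40 1, 45 without LQ-40 2 and 155 without LQ-40 3. It was 48 without a filter and 14 in a fit of the 2 groups alone, where the calls of Hspa5, Iigp1, Adamts4, Cdkn1a and Vegfa were lost (adjusted p between 0.0644 for Hspa5 and 0.137 for Vegfa; over all alternatives these values ranged from 0.000182 for Hspa5 upwards). Among the lists with at least 4 tested members 20 passed, 11 without LQ-40 1, and 1, protein folding stress, passed with an estimated correlation.

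The same comparison was made for the second compound, SQ-3 against Model. Clock genes again rose and fell in both directions. Dbp averaged 35.8 ± 3.65 in SQ-3 and 4.14 ± 1.81 in Model hearts (7.43-fold higher, log2 2.89, SE 0.21, adjusted p = 0.00051). Tef rose 2.99-fold and Per3 2.77-fold (adjusted p = 0.000794 for both), and Nr1d2, a nuclear receptor that represses Arntl, rose 2.39-fold (30.7 ± 1.39 against 12.3 ± 1.67, adjusted p = 0.00146). Nfil3 was 3.90-fold lower (adjusted p = 0.000794) and Arntl 3.19-fold lower (adjusted p = 0.00123). Of 16 clock genes 6 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.000302, adjusted p = 0.238 with an estimated correlation).

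In SQ-3 hearts the protein folding list was lower than in Model hearts. Hspa5 averaged 96.8 ± 6.70 against 230.7 ± 7.14 in Model hearts (2.37-fold lower, log2 -1.25, SE 0.13, adjusted p = 0.0016), Hyou1, outside this list, was 2.68-fold lower (adjusted p = 0.00295) and the cytosolic Hsph1 2.19-fold lower (adjusted p = 0.00464). In the protein folding stress list 5 of 17 genes fell (13 adjusted over the list alone; median -0.56, adjusted p = 1.98e-12, adjusted p = 0.00168 with an estimated correlation). Nr4a3 was 2.59-fold lower (adjusted p = 0.00132). The immediate early list was lower (median -0.94, adjusted p = 6.57e-09, adjusted p = 0.492 with an estimated correlation), with 0 of 15 genes called by limma, 0 by limma-voom, 13 at an unadjusted p under 0.05 and 12 adjusted over the list alone. Egr2, a member, averaged 1.92 ± 1.09 (log2 against Model -1.12, adjusted p = 0.15).

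Collagen genes of SQ-3 hearts lay below Model levels without passing singly. Col1a1 averaged 355.0 ± 64.7 (log2 against Model -1.31, 95% interval -2.56 to -0.06, adjusted p = 0.334), Col3a1 562.1 ± 42 (-0.99, 0.364), Fn1 83.0 ± 5.73 (-0.88, 0.353) and Eln 96.2 ± 45.1 (-1.04, 0.203). Postn averaged 153.2 ± 64.3 (-0.33, 0.8), Acta2 116.9 ± 28.7 (-0.54, 0.213), Tgfb1 9.71 ± 0.782 (-0.40, 0.334) and Tgfb3 33.3 ± 7.11 (-0.85, 0.291). SQ-3 and Model libraries did not overlap for these genes except Postn, while 26.4% of all genes had no overlap. Over the alternatives adjusted p ranged from 0.054 to 0.626 for Col1a1, 0.0521 to 0.652 for Col3a1 and 0.0659 to 0.635 for Fn1. The collagen and structural matrix list was lower (median -0.69, adjusted p = 2.11e-07, adjusted p = 0.556 with an estimated correlation), with 0 of 32 members called by limma, 0 by limma-voom, 9 at an unadjusted p under 0.05, all lower, and 0 adjusted over the list alone. In the matrix-modifying list (adjusted p = 1.69e-05, adjusted p = 0.556 with an estimated correlation) 1 of 29 genes fell (7 adjusted over the list alone). It was Adamts4, 3.37-fold lower (adjusted p = 0.0112), a call lost without Model 1 (0.0665), Model 3 (0.0696), SQ-3 1 (0.0634) or SQ-3 2 (0.0515) and with a pseudocount of 0.1 (0.114), in a range of 0.0085 to 0.114. The activated fibroblast list (median -0.67, adjusted p = 0.00229) and the TGF-beta list (median -0.36, adjusted p = 0.00178) were lower with 0 genes called by limma or limma-voom, 4 each at an unadjusted p under 0.05 and 0 adjusted over the list alone; for both, adjusted p = 0.556 with an estimated correlation.

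Lists of energy metabolism and contraction were higher in SQ-3 than in Model hearts, again without single calls. They were oxidative phosphorylation (median 0.47, adjusted p = 6.57e-09), fatty acid oxidation (0.52, adjusted p = 0.000136) and contractile genes (0.41, adjusted p = 2.36e-05), each with adjusted p = 0.556 with an estimated correlation, 0 genes called by limma or limma-voom and 2, 4 and 2 at an unadjusted p under 0.05. Ndufb5 averaged 47.5 ± 5.16 (log2 against Model 0.58, adjusted p = 0.298) and Tnnc1, cardiac troponin C, 1378 ± 113 (0.52, 0.331). Interferon genes were higher as a list (median 0.27, adjusted p = 0.00249, adjusted p = 0.556 with an estimated correlation), with 0 of 20 called by limma or limma-voom and 2 at an unadjusted p under 0.05; Rsad2 averaged 3.09 ± 0.481 (log2 0.59, adjusted p = 0.286). Cell cycle genes (median -0.27, adjusted p = 0.000302) and cardiac stress genes (median -0.63, adjusted p = 0.0282) were lower as lists, both with adjusted p = 0.556 with an estimated correlation and 0 calls by limma or limma-voom, against 2 and 4 at an unadjusted p under 0.05 (for cardiac stress 1 higher and 3 lower, also when adjusted over the list alone). Mitochondrially encoded genes were higher (median 0.35, adjusted p = 0.00583) and glucocorticoid-responsive genes lower (-0.31, 0.0299) as lists, with 0 calls by limma, 0 and 1 by limma-voom, and 1 and 3 at an unadjusted p under 0.05; for both, adjusted p = 0.556 with an estimated correlation. Without Model 3 the interferon, cardiac stress and glucocorticoid-responsive lists did not pass (medians 0.09, -0.40 and -0.17), nor did the mitochondrially encoded list without Model 1 (0.17) or SQ-3 3 (0.18). Gdf15 averaged 3.11 ± 2.35 (log2 -2.49, adjusted p = 0.0566, range 0.0465 to 0.247 over the alternatives, passing without SQ-3 2), Rcan1 43.4 ± 4.95 (-1.12, 0.0538), Vegfa 28.3 ± 1.89 (-0.67, 0.0538) and Cdkn1a 14.7 ± 3.11 (-1.18, 0.0534). Rcan1, Vegfa and Cdkn1a passed with a mean of at least 5 FPKM (0.0428, 0.0428 and 0.039), Vegfa (0.0372) and Cdkn1a (0.0423) with quantile normalization and Cdkn1a with limma-voom (0.0397), with highest values of 0.247, 0.247 and 0.195 over the alternatives. Nppa averaged 1439 ± 1548 (log2 -0.80, adjusted p = 0.633), Nppb 467.9 ± 435.0 (-0.97, 0.47), Myh7 73.4 ± 15.9 (0.71, 0.212) and Myh6 2350.0 ± 660.4 (0.49, 0.479). Cd14 averaged 21.1 ± 4.65 (-0.92, 0.146), and the macrophage list did not pass (adjusted p = 0.141). Median, mean and test differed in sign for neutrophil (0.15, 0.03, down) and MHC class II genes (-0.05, 0.27, up), which did not pass.

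In all, 10 genes rose and 35 fell in SQ-3 against Model hearts, and 26.4% of genes had groups that did not overlap, where chance gives 10%. The count of 45 became 17 without Model 1, 23 without Model 2, 12 without Model 3, 14 without SQ-3 1, 26 without SQ-3 2 and 17 without SQ-3 3. In a fit of the 2 groups alone it was 62, whereas the LQ-40 count in such a fit was 14. Among the lists with at least 4 tested members 15 passed and 1, protein folding stress, passed with an estimated correlation.

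Both compounds were set against the Model change itself. Of the genes that rose in Model hearts 61 fell back with LQ-40 and 35 with SQ-3, and of those that fell in Model hearts 22 and 10 rose (149 and 90, and 66 and 25, adjusted over the list alone). The total was 83 for LQ-40 and 45 for SQ-3, in the direction of Sham, which does not say that the genes ended at Sham levels. Hspa5, for example, lay below all Sham libraries in each treated library. Over all Model genes 90.5% had the opposite sign in LQ-40 and 96.4% in SQ-3 against Model. With treated groups simulated as equal to Model, 100 times, these shares averaged 46.2% and 48.7% and reached 88.6% and 89.7%, and the counts of genes moved back averaged 0.12 and 1.84 and reached 8 and 134. The simulated shares used the genes called in the observed data, not genes selected anew in each simulation. They therefore leave out opposite signs that come from selecting genes on the Model libraries. The correlation of log2 changes across genes, which are not independent replicates, was -0.66 between LQ-40 against Model and Model against Sham (simulated mean -0.11, from -0.75 to 0.46; covariance -0.153 against a simulated mean of -0.0263, from -0.231 to 0.099) and -0.73 for SQ-3 (simulated mean -0.13, from -0.75 to 0.42; covariance -0.17 against -0.0277, from -0.249 to 0.092), so these values lay within the simulated ranges. The Model libraries are shared by both sides of these comparisons, so part of the correlation, of the opposite signs and of the counts may come from shared controls. The simulation holds these shared libraries but no effect of a compound. It called 0.15 genes on average and up to 10 for LQ-40 against Model, where 87 were observed. For SQ-3 against Model it called 12.45 on average and up to 1194, where 45 were observed. The SQ-3 counts of calls and of genes moved back thus lay within the simulated ranges. The highest simulated counts, 1194 and 134, each came from a single simulation that made up most of the mean. Counts as high as those observed were therefore rare among the 100 simulations. The LQ-40 count of 83 became 54 without Model 1, 30 without Model 3, 46 without LQ-40 1, 39 without LQ-40 2 and 153 without LQ-40 3. The SQ-3 count of 45 became 17 without Model 1, 23 without Model 2, 12 without Model 3, 13 without SQ-3 1, 26 without SQ-3 2 and 17 without SQ-3 3.

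Both compounds called 37 of the same genes in the same direction, 8 up, with Dbp, Tef and Per3 among them, and 29 down, with Hspa5, Arntl and Nfil3 among them. Independent lists of these sizes would share 0.188 genes, a value that leaves out the shared Model libraries. The simulated groups shared 0, but their LQ-40 calls averaged 0.15. With so few calls little could be shared, so this gives no chance value for the 37. The correlation between both contrasts was 0.75 (simulated mean 0.49, from -0.21 to 0.95), with a covariance of 0.0816 against 0.0337 simulated. Part of the overlap may come from the shared Model libraries. The shared count became 15 without Model 1, 20 without Model 2, 12 without Model 3, 58 without LQ-40 3, 13 without SQ-3 1, 21 without SQ-3 2 and 17 without SQ-3 3.

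**Figure D2:**
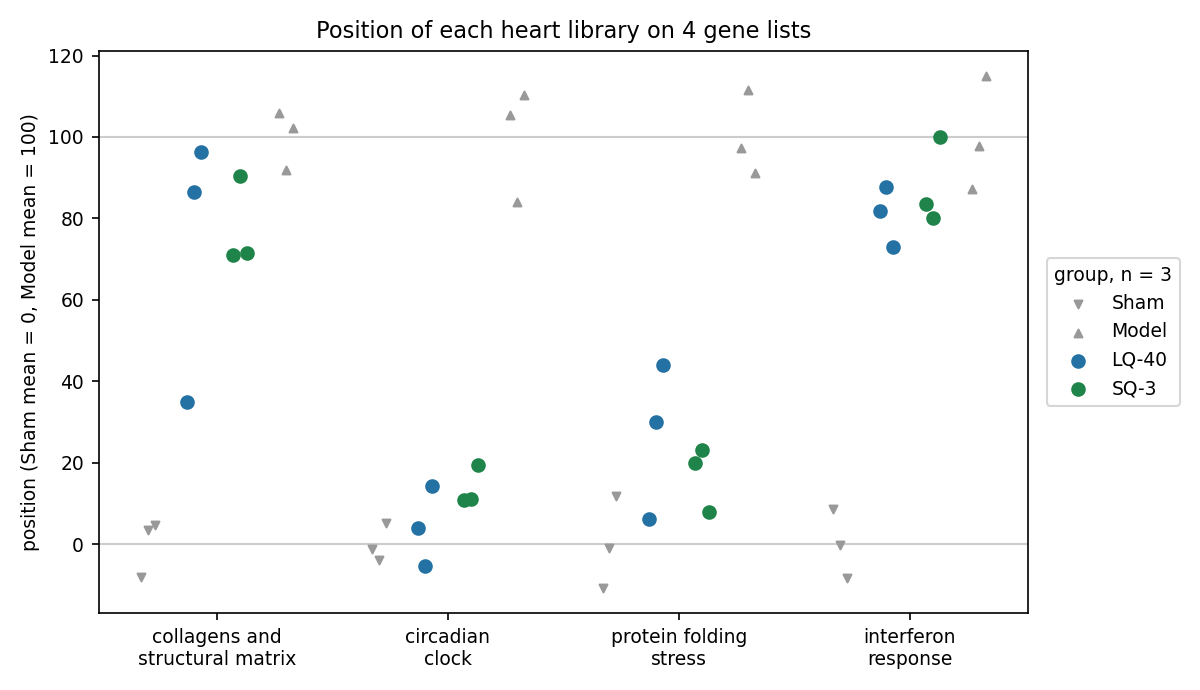
Position of each treated heart library on 4 gene lists, on a scale where the Sham mean is 0 and the Model mean is 100; points are libraries of LQ-40 and SQ-3 (3 each), small grey marks the Sham and Model libraries. Clock positions ran from -5.4 to 19.5, collagen positions from 34.8 to 96.2.

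LQ-40 and SQ-3 hearts were compared directly, with the limit that the labels used here state no doses. No gene differed by limma at an adjusted p of 0.05 (0 of 13000, smallest adjusted p = 1), 394 passed an unadjusted p under 0.05, and limma-voom also called 0. The groups did not overlap for 795 genes, or 6.1%, where chance gives 10%. The count was 2 without a filter and 1 without SQ-3 1. The median 95% interval reached 0.34 on the log2 scale to either side, so many moderate differences were within the error. Dbp, Hspa5 and other shared genes were in this sense not shown to differ, which does not show that the compounds act alike.

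For the matrix genes the difference of LQ-40 minus SQ-3 hearts was 0.39 on the log2 scale for Col1a1 (95% interval -0.86 to 1.65), 0.31 for Col3a1 (-0.72 to 1.33), 0.61 for Fn1 (-0.28 to 1.5) and -0.33 for Postn (-1.61 to 0.95). It was 0.04 for Acta2 (-0.32 to 0.39), -0.01 for Tgfb1 (-0.39 to 0.38), -0.45 for Nppa (-2.19 to 1.29), -0.80 for Nppb (-2.18 to 0.59), -0.64 for Myh7 (-1.10 to -0.17) and -0.22 for Myh6 (-0.94 to 0.51), all with an adjusted p of 1. Signs of these differences turned when 1 library was left out, for Col1a1 (-0.11 without LQ-40 3), Col3a1 (-0.21 without LQ-40 3), Postn (0.47 without LQ-40 1), Nppa (0.24 without LQ-40 1 and 0.42 without SQ-3 2) and Myh6 (0.13 without LQ-40 3), and for Acta2 (-0.11 without SQ-3 1) and Tgfb1 (0.10 without LQ-40 1), both near 0 throughout.

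The genes with the smallest unadjusted p on the higher side in LQ-40 were Npy1r, a neuropeptide Y receptor (1.82 ± 0.265 against 0.616 ± 0.169 scaled FPKM, log2 0.80, interval 0.50 to 1.11), Xdh (0.72, 0.38 to 1.07), the interferon-induced GTPases Gbp3 (1.02, 0.52 to 1.51) and Tgtp2 (1.21, 0.59 to 1.82; uncertain, as Tgtp1 is a near-identical copy), and Tbl1xr1 (0.43, 0.21 to 0.65). On the lower side they were Leng8 (-0.33, -0.53 to -0.14), Fam58b (-0.44, -0.70 to -0.18), B3gnt3 (-0.60, -0.95 to -0.24), Hey2 (-0.41, -0.65 to -0.16) and Snx32 (-0.45, -0.73 to -0.17). None passed adjustment. The clock gene Per2 averaged 8.22 ± 2.08 and 3.55 ± 1.10 (log2 1.02, interval 0.48 to 1.57), the only clock member to pass adjusted over the list alone. Ccl8, a monocyte chemokine, averaged 47.5 ± 33.8 and 16.8 ± 4.05 (1.25, 0.21 to 2.29), and S100a8 13.2 ± 10.6 and 2.19 ± 0.72 (1.60, -0.01 to 3.21).

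By list, LQ-40 hearts lay higher for cytokines and chemokines (median 0.42, adjusted p = 2.26e-05), neutrophil genes (1.03, 0.000271), macrophage genes (0.34, 0.000154), interferon response (0.24, 0.00234), MHC class II (0.54, 0.00329), erythroid (0.65, 0.00283) and cell cycle genes (0.20, 0.000156). They lay lower for oxidative phosphorylation (-0.24, 2.26e-05), contractile genes (-0.22, 0.000275), cardiac stress genes (-0.40, 0.000365) and fatty acid oxidation (-0.20, 0.0424). None of these 11 lists passed with an estimated correlation (adjusted p = 0.828 to 0.852 with an estimated correlation). Of the 10 splits of these libraries into groups of equal size, 9, the real one included, passed at least as many lists, and another passed 15. Without LQ-40 3 only 4 of them passed; the medians became 0.02 for oxidative phosphorylation, 0.03 for contractile genes, 0.10 for fatty acid oxidation and 0.04 for macrophage genes. Without LQ-40 1 the cardiac stress (0.06), erythroid (0.16) and cell cycle lists (0.16) did not pass. The collagen list did not pass (median -0.04, adjusted p = 0.672), nor did clock genes (0.124) or protein folding genes (0.472). Median, mean and test differed in sign for the TGF-beta (0.01, -0.02, up) and Schwann cell lists (-0.01, 0.04, up).

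Treated hearts were last compared with Sham hearts. The matrix genes stayed higher. Col1a1 was 6.57-fold higher in LQ-40 (adjusted p = 0.0158) and 5.01-fold higher in SQ-3 hearts (0.0375), Col3a1 6.47-fold (0.00804) and 5.23-fold (0.0182), Fn1 11.5-fold (0.0012) and 7.56-fold (0.0033), and Postn 8.4-fold (0.0111) and 10.6-fold (0.00975). For LQ-40 the Col1a1 call was lost without Sham 1 (0.055), LQ-40 2 (0.0636) or LQ-40 3 (0.0574) and in a fit of the 2 groups alone (0.0919), in a range of 0.000919 to 0.0919. For SQ-3 the Col1a1 call was lost without any 1 of Sham 1 (0.123), Sham 2 (0.0785), Sham 3 (0.0554), SQ-3 1 (0.0995), SQ-3 2 (0.0904) or SQ-3 3 (0.0929), with quantile normalization (0.059) and without a filter (0.103), in a range of 0.0244 to 0.123. The Col3a1 call was lost without Sham 1 (0.0674), Sham 2 (0.0504), SQ-3 1 (0.0565), SQ-3 2 (0.0609) or SQ-3 3 (0.053) and without a filter (0.0616), in a range of 0.00777 to 0.0674. In the fit of the 2 groups alone Col3a1 and Postn were lost for LQ-40 (0.0707 and 0.0725, the highest of their alternatives, with lowest values of 0.000466 and 0.000215). Of 32 collagen and structural matrix genes 28 were higher in LQ-40 (adjusted p = 2.04e-16, adjusted p = 0.499 with an estimated correlation) and 27 in SQ-3 hearts (adjusted p = 9.14e-21, adjusted p = 0.485 with an estimated correlation).

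Other fixed genes did not pass against Sham in either group. In LQ-40 hearts the log2 difference was -0.07 for Acta2 (adjusted p = 0.797), 0.54 for Tgfb1 (0.0568), 1.44 for Nppa (0.211), 0.66 for Nppb (0.48), -0.21 for Myh7 (0.499) and -0.95 for Myh6 (0.0671). In SQ-3 hearts it was -0.10 for Acta2 (0.706), 0.55 for Tgfb1 (0.0848), 1.90 for Nppa (0.151), 1.46 for Nppb (0.162), 0.43 for Myh7 (0.21) and -0.74 for Myh6 (0.174). Tgfb1 passed without Sham 3 for both (0.0276 and 0.0358), and for LQ-40 without LQ-40 1 (0.0243) and with a mean of at least 5 FPKM (0.0475), and Myh6 without LQ-40 1 (0.0125). Over all alternatives Tgfb1 ranged from 0.0243 to 0.207 for LQ-40 and from 0.0358 to 0.239 for SQ-3, and Myh6 from 0.0125 to 0.508 for LQ-40. Acta2 turned sign with quantile normalization (0.14 in LQ-40 and 0.04 in SQ-3 hearts) and without SQ-3 1 (0.05). All 20 interferon genes stayed lower than in Sham hearts in both groups (medians -2.10 and -2.36; adjusted p = 1.89e-22 and 3.66e-29; adjusted p = 0.355 and 0.181 with an estimated correlation). Among clock genes limma called 0 of 16 in both, 2 and 9 passed an unadjusted p under 0.05, 0 and 8 (4 up and 4 down) passed adjusted over the list alone, and limma-voom called 0 and 2 (list adjusted p = 0.845 and 0.197). Of 17 protein folding genes limma called 1 higher and 3 lower in LQ-40 hearts and 2 lower in SQ-3 hearts.

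In all, 1278 genes were higher and 771 lower in LQ-40 than in Sham hearts, and 632 were higher and 236 lower in SQ-3 hearts. The difference between these counts is not a test of the compounds. The LQ-40 count of 2049 became 518, 648 and 1142 without Sham 1, 2 and 3, and 4372, 408 and 523 without LQ-40 1, 2 and 3. The SQ-3 count of 868 became 261, 227 and 444 without Sham 1, 2 and 3, and 321, 247 and 252 without SQ-3 1, 2 and 3.

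**Figure D3:**
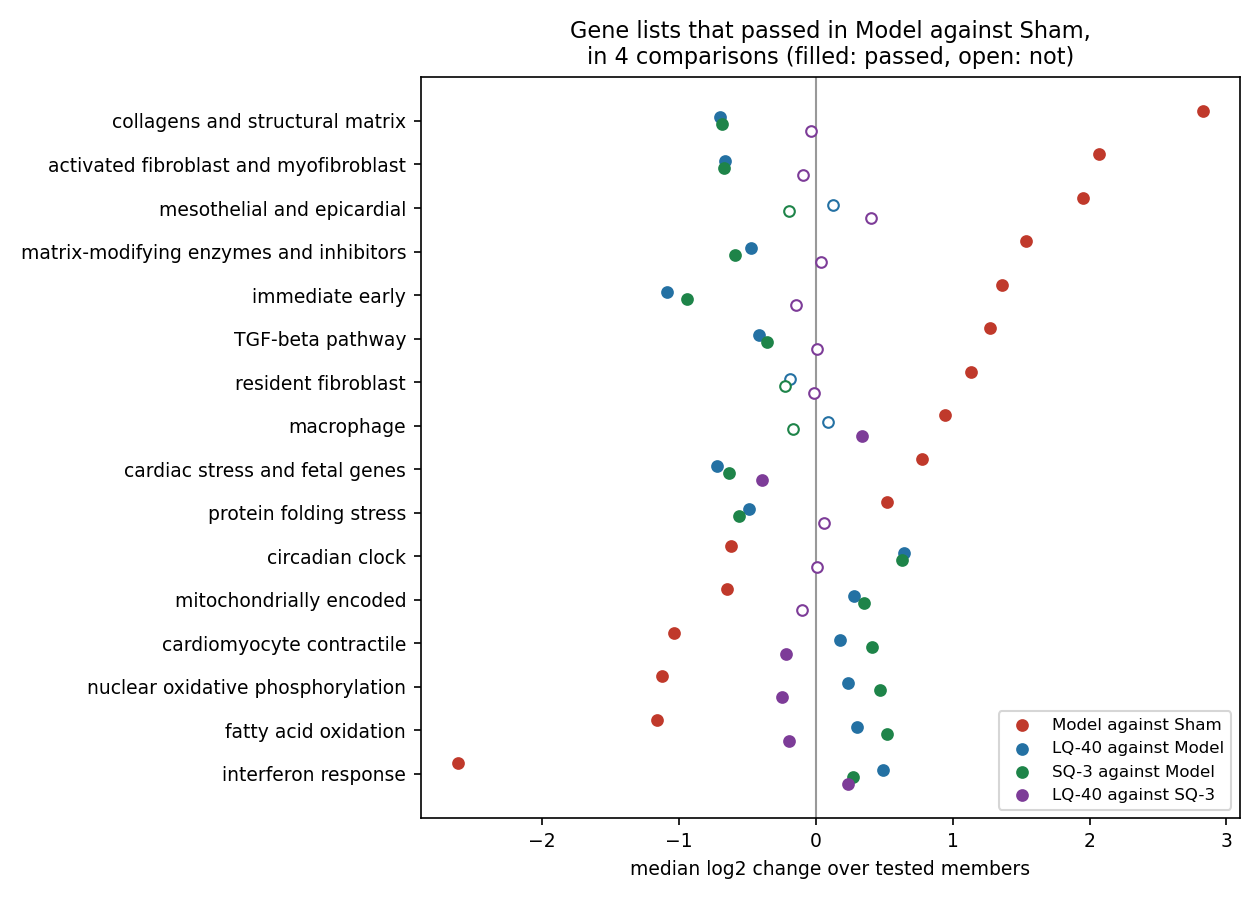
Median log2 change of 16 gene lists in 4 comparisons of mouse hearts (Model against Sham, each compound against Model, and LQ-40 against SQ-3); each point is the median over the tested members, and filled points passed camera with a preset correlation of 0.01. The collagen list had a median of 2.83 in Model against Sham and -0.70 and -0.69 in the compounds against Model.

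The rat cells were compared to ask how the 3 cell types interact in a 3D co-culture, against 2D cells. There was 1 library of each kind, so no difference here has a replicate check or a p-value. The design text gives the 3D culture the code 3D-OGD-MF, and the labels do not say whether both cultures were kept at the same oxygen level. The 2D library held 13262387 reads and the 3D library 11910160, with mitochondrial shares of 2.73% (exact Clopper-Pearson 95% interval 2.72 to 2.74) and 2.45% (2.45 to 2.46). Intervals and floors here cover counting error only.

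Inflammatory mediators were much higher in the 3D library. Csf2, the cytokine GM-CSF (chromosome 10, 39602089 to 39604070, Rnor_6.0), had 0 reads in 2D and 343 in 3D, at least 132.8-fold higher against a floor of 3 reads in the 2D library. Cxcl10, an interferon-induced chemokine, was at 6.51 and 275.1 scaled FPKM (ratio 42.2, 95% interval 34.6 to 52.1), Il1b had 7 and 582 reads (ratio 96.6, 46.6 to 241), and Cx3cl1 64 and 2358 reads (ratio 42.8, 33.4 to 55.7). Ccl4 had 3 and 413 reads (ratio 160, interval 54.3 to 778), Ccl5 1 and 152 (ratio 177, 31.2 to 7018) and Cxcl2 1 and 867 (ratio 1007, 180 to 39816). Of 19 measured cytokine and chemokine genes 17 were at least 2-fold higher, with a median of 8.33-fold (log2 3.06, above 100% of 10000 random lists matched on expression).

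Interferon response genes were also higher, with 15 of 18 measured members at least 2-fold apart (median log2 1.78, percentile 100). Rsad2, an antiviral enzyme, had 61 and 2235 reads (ratio 42.6, 33.0 to 55.8) and Ifit3 14 and 885 (ratio 73.4, 43.5 to 134.8). Gbp5, an interferon-induced GTPase outside the list, had 10 and 2160 reads (ratio 251, 136 to 524), and Serpinb2, a plasminogen activator inhibitor, 23 and 2147 (ratio 108, 72.1 to 171). Hypoxia and glycolysis genes had 5 of 25 at least 2-fold higher (median 0.24, percentile 100), among them Egln3, an oxygen sensor (15 and 421 reads, ratio 32.6, 19.5 to 58.8), and the glucose transporter Slc2a1 (414 and 1308 reads, ratio 3.67, 3.28 to 4.11). Immediate early genes had 4 of 16 (median 0.38, percentile 100), with Atf3 at a ratio of 3.99 (3.07 to 5.26). Clock genes had 1 of 15 (median 0.49, percentile 100), which was Bhlhe41 (ratio 2.67, 2.22 to 3.23). The neutrophil list, of which 4 members were measured, had a median of 0.82 (percentile 99.1), with Lcn2, an iron-binding protein of neutrophils and other cells, at 12.8 (9.29 to 18.1). Of the others, S100a9 (40 and 68 reads) and Camp (4 and 12) were higher and S100a8 (17 and 6) lower. A further 5 matched members stayed below 1 FPKM. Csf3r (31 and 6 reads), Mmp8 (21 and 4), Cxcr2 (5 and 2) and Ngp (4 and 0) were lower in 3D, and 1 had no reads. Neutrophil genes thus did not rise as a whole.

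Matrix genes differed little. Col1a1 was at 2007 and 1788 scaled FPKM (ratio 0.891, 0.884 to 0.898), Col3a1 at 211.9 and 198.4 (0.936), Fn1 at 533.4 and 619.2 (1.16), Acta2 at 821.7 and 795.2 (0.968) and Tgfb1 at 90.6 and 119.96 (1.32, 1.26 to 1.4). Postn was at 140.2 and 278.7 (1.99, 1.93 to 2.05). Of 27 collagen and structural matrix genes 2 were at least 2-fold higher (median 0.09, percentile 82.6), with Dcn, the proteoglycan decorin, at 3.31 (3.14 to 3.49). Of 26 matrix-modifying genes 3 were at least 2-fold higher and 1 lower (median 0.06, percentile 66.0), with Mmp9 at 9.72 (7.15 to 13.5) and Mmp12 at 13.8 (7.26 to 29.6). Of 11 activated fibroblast genes 1 was at least 2-fold higher, Tnc (3.78, 3.58 to 4.0; list percentile 47.5), and of 11 resident fibroblast genes 3 were higher and 2 lower (median 0.44, percentile 100), with Pdgfra at 2.94 (2.59 to 3.33). The TGF-beta list had a median of -0.09 (percentile 1.7), with 1 of 22 genes at least 2-fold higher, Inhba (2.13, 2.00 to 2.27), and 1 lower, Tgfb3 (2.57-fold lower, 2.35 to 2.83). Angptl4, in the glucocorticoid-responsive list (2 of 9 up, percentile 67.3), had a ratio of 11.8 (9.43 to 15.0).

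Lower in the 3D library were cell cycle genes, with 0 of 20 at least 2-fold apart (median -0.36, percentile 0.0), such as Bub1 (1.39-fold lower, 1.26 to 1.52) and Rrm2 (1.35-fold lower, 1.26 to 1.46), and cardiac stress and fetal genes (1 of 7 up, median -0.36, percentile 0.4), such as Ankrd1 (1.99-fold lower, 1.87 to 2.11). Single genes far lower in 3D were Ndufa1, a complex I subunit (237 and 3 reads, ratio of 2D to 3D 68.0, 23.0 to 332), Nhp2 (400 and 7 reads, 49.2, 23.7 to 123), Tspan4 (4.92, 4.06 to 6.0), Lmod1 (3.81, 2.79 to 5.28) and Pik3ip1 (3.47, 2.88 to 4.21). Nppb had 15 and 28 reads, and Myh6 was at 1.95 and 1.58 scaled FPKM (159 and 111 reads).

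Other lists lay within the middle of matched random lists. Percentiles were 56.5 for contractile genes (7 measured, 0 at least 2-fold apart), 83.2 for macrophage (12 measured, 0), 65.4 for endothelial (8 measured, 0), 52.4 for smooth muscle and pericyte (1 of 9 lower), 88.1 for mesothelial (4 measured), 18.1 for fatty acid oxidation (15 measured), 29.8 for oxidative phosphorylation (25 measured), 34.0 for protein folding (16 measured) and 17.7 for xenobiotic genes (1 of 13 lower). T and B lymphocyte, adipocyte, atrial, skeletal muscle, Schwann cell and sex-linked lists had 1, 3, 1, 3, 1 and 2 measured members and were given no percentile, and erythroid and MHC class II lists had 0. No gene name of the rat table matched the mitochondrially encoded list.

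In all, 674 of 13405 genes were at least 2-fold higher and 327 at least 2-fold lower in the 3D library. With a pseudocount of 0.1 these were 951 and 571, and among genes of at least 5 FPKM 334 and 91.

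**Figure D4:**
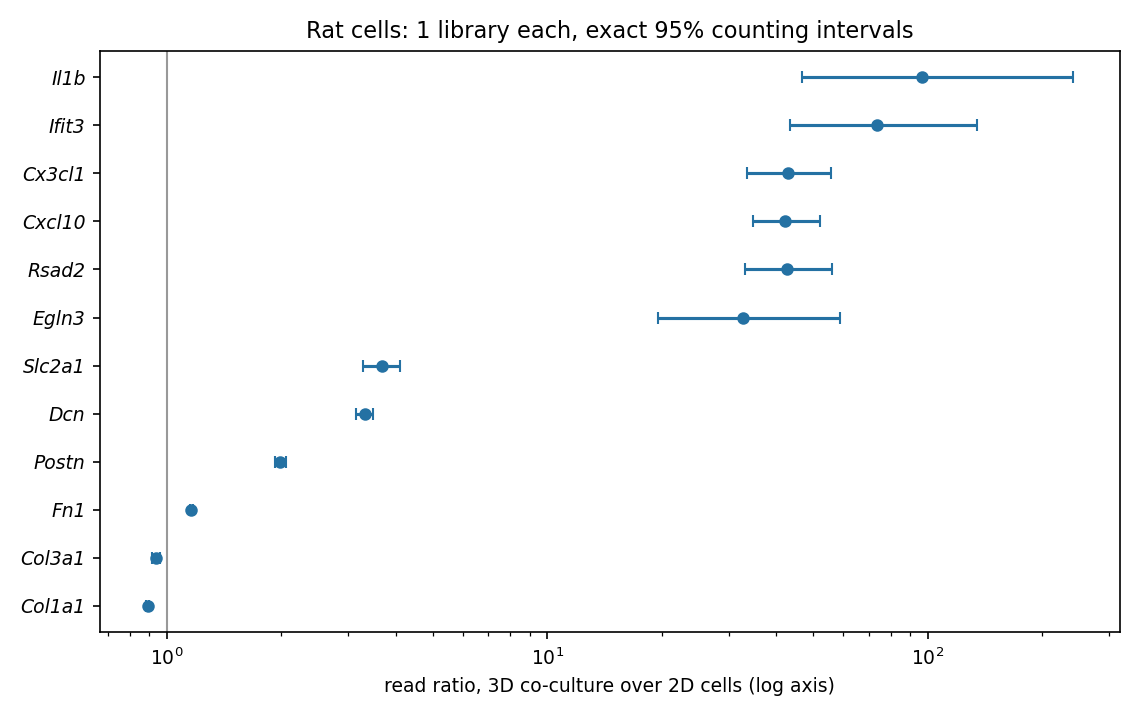
Read ratio of the 3D co-culture over the 2D cells for 12 rat genes on a log axis, 1 library each; points are ratios and whiskers exact 95% intervals that cover counting error only. Cxcl10 lay at 42.2 (34.6 to 52.1) and Col1a1 at 0.891 (0.884 to 0.898).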

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

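The splits of the samples behind the gene counts were chosen as tests only after the counts were seen; every alternative setting and the splits behind the list counts were chosen before. Of 158 mouse gene and comparison pairs named in the text, 86 were called, 69 of them kept the call in every alternative that tested them and 0 changed sign. FPKM as deposited moved no count of calls by over 1.5 times and changed no call of a named gene, and limma-voom ended no such call. FPKM as deposited is a weak check of scaling, as the median-of-ratios factors of the mouse libraries ran only from 0.979 to 1.032. The 40 rat genes kept their sign under each scaling, pseudocount and filter.

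Counts of called genes moved by over 1.5 times under settings that change which genes or libraries enter or how strict the limit is; for the estimated correlation and the pseudocount the cause was not tested. With a mean of at least 5 FPKM, which tests fewer genes, Model against Sham called 3284 genes and 12 lists passed for LQ-40 against Model and 7 for LQ-40 against SQ-3. A log2 fold change of at least 1 left 1454 genes for Model against Sham, 52 and 26 for LQ-40 and SQ-3 against Model, 604 and 402 against Sham, 47 and 21 moved back and 23 shared. No filter, which tests more low genes, gave 48 genes for LQ-40 against Model, 2 for LQ-40 against SQ-3, 774 and 262 for LQ-40 and SQ-3 against Sham, and 46 moved back by LQ-40. Fits of only the 2 groups compared gave 14 genes for LQ-40 against Model and 230 for LQ-40 against Sham. In the same fits the counts rose to 62 for SQ-3 against Model, 1292 for SQ-3 against Sham and 5412 for Model against Sham. Fewer libraries behind the spread therefore do not by themselves account for the falls. Which compound had more calls against Model turned with this setting. The main fit assumes an equal spread in all groups. On the first principal component LQ-40 libraries ran from -20.6 to 34.3 and SQ-3 libraries from 0.2 to 17.7. Counts and adjusted p of the main fit for the compounds rest on that assumption, and its part in these shifts was not tested. With an estimated correlation camera passed 0, 1, 1 and 0 lists in Model against Sham, LQ-40 against Model, SQ-3 against Model and LQ-40 against SQ-3, in place of 16, 20, 15 and 11. For the rat, a pseudocount of 0.1 gave 1522 genes 2-fold apart and a floor of 5 FPKM 425, in place of 1001.

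Leaving out 1 library left 3288 to 4498 calls for Model against Sham, 31 to 155 for LQ-40 against Model, 12 to 26 for SQ-3 against Model, 0 to 1 for LQ-40 against SQ-3, 408 to 4372 for LQ-40 against Sham and 227 to 444 for SQ-3 against Sham. Genes moved back numbered 30 to 153 for LQ-40 and 12 to 38 for SQ-3, and shared genes 12 to 58. Lists numbered 16 to 17, 11 to 21, 13 to 16 and 10 to 14 for the first 4 comparisons, but were not always the same ones: of those that passed with all libraries 15 to 16 of 16, 9 to 19 of 20 (9 without LQ-40 1), 12 to 14 of 15 and 4 to 10 of 11 (4 without LQ-40 3) were kept. These fits hold fewer libraries; why some counts rose, to 155 without LQ-40 3 and to 4372 without LQ-40 1, was not tested.

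Among the named genes only uncalled ones changed sign, and the cause was not tested. Leaving out 1 library gave, for LQ-40 against Model, -0.71 to 0.31 for Fn1, -1.29 to 0.13 for Postn, -0.12 to 0.25 for Myh7 and -0.01 to 0.63 for Myh6. For LQ-40 against SQ-3 it gave -0.11 to 1.05 for Col1a1, -0.21 to 0.85 for Col3a1, -0.95 to 0.47 for Postn, -0.11 to 0.22 for Acta2, -0.11 to 0.10 for Tgfb1, -1.13 to 0.42 for Nppa and -0.50 to 0.13 for Myh6. For SQ-3 against Sham it gave -0.289 to 0.046 for Acta2, which quantile normalization put at 0.042, and at 0.138 in LQ-40 against Sham.

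With the replicate number as a replicate block, SQ-3 against Model called 29 genes and 29 moved back, in place of 45 each; LQ-40 against Model called 59 and Model against Sham 4576. For LQ-40 against Model it ended the calls of Nr4a1 (adjusted p = 0.0892, range 0.0244 to 0.164) and Gdf15 (adjusted p = 0.0584, range 0.0118 to 0.166), and for LQ-40 against Sham Tgfb1 passed (adjusted p = 0.0434, range 0.0243 to 0.207). The numbers share no stated origin, and libraries of the same number did not deviate together: 3 of 18 pairs had a correlation over 0.1 (from -0.268 to 0.219), and 0 of 12 libraries correlated best with their own number.

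The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Real counts of genes and the highest of the other splits were 5053 and 1 for Model against Sham, 87 and 2 for LQ-40 and 45 and 0 for SQ-3 against Model, and 2049 and 1 for LQ-40 and 868 and 1 for SQ-3 against Sham, so that 1 of 10 splits, the real one, gave as many in each. For LQ-40 against SQ-3 they were 0 and 1134, and all 10 splits gave as many. The split with 1134 set LQ-40 1, SQ-3 1 and SQ-3 3 against the rest. It was picked as the highest, and groups simulated without an effect reached 1194 calls for SQ-3 against Model, in a single one of 100 simulations. A structure of the samples that does not follow the compound is therefore possible but not shown by this count. For lists they were 16 and 19 (2 splits with as many) in Model against Sham, 20 and 18 (1 split) and 15 and 18 (4 splits) for LQ-40 and SQ-3 against Model, and 11 and 15 (9 splits) for LQ-40 against SQ-3. Calls of low genes are limited by depth, since 1 read per kilobase was worth up to 0.0805 FPKM.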

Other observations

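Of the tests below, those of scaling and of atrial tissue in the LQ-40 hearts were chosen before their results were seen; all others were chosen only after.

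Both rat libraries, made from cardiomyocytes, cardiac fibroblasts and bone-marrow derived macrophages, held few transcripts of most contractile genes. Of 19 matched ones 7 reached 1 FPKM in either library. Myl2, the ventricular light chain, had 0 reads in both libraries, Ryr2, the calcium release channel, 4 in 2D and 2 in 3D, Tnni3 6 and 2, Actc1 10 and 6, Tnnt2 107 and 96 and Myh6 159 and 111, whereas Tnnc1 had 281 and 227, Casq2 1411 and 1059, Tpm1 5946 and 6127 and Atp2a2 7297 and 7604. Of 20 matched macrophage genes 12 reached 1 FPKM. Spp1 stood at 297.04 and 256.04 FPKM, Gpnmb at 332.99 and 318.21 and Lgals3 at 277.46 and 251.07, whereas Csf1r had 207 and 113 reads, C1qa 1 and 1 and Cx3cr1 0 and 0. Fibroblasts also express Spp1, Lgals3, Tpm1 and Atp2a2, so these levels do not give the share of a cell type.

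Clock and protein folding genes, taken as lists, lay nearer to Sham than to Model levels in the treated hearts. Even so, 4 clock members were higher and 4 lower in SQ-3 than in Sham hearts when adjusted over the list alone. Limma called 4 of 17 protein folding genes apart from Sham in LQ-40 hearts, all but 1 of them lower, and 2 in SQ-3 hearts, which were lower. Hspa5 was at 87.5 to 108.0 scaled FPKM in the treated libraries and 115.9 to 134.9 in Sham libraries. Hsph1 was at 5.29 to 6.08 and 7.64 to 11.7, so the list position hides members that passed below Sham. On a scale with Sham at 0 and Model at 100 the 6 treated libraries lay between -5.4 and 19.5 for the clock list, 6.2 and 44.1 for protein folding and 34.8 and 96.2 for collagens. The tables argue against clock genes that merely follow matrix remodelling, since the collagen position exceeded the clock position by at least 29.0 points in each treated library, whichever Sham or Model library was left out of the scale, and Sham or Model libraries left out differed by up to 12.5. For protein folding genes this gap was at least 45.9 points in 5 treated libraries, against up to 26.7 in those left out, which argues against it there, and at least 23.8 in LQ-40 1 (28.6 with all libraries in the scale), where it stays open. Another time of day at collection of the Model hearts stays a candidate explanation for the clock genes. As the labels used here hold no collection time, it cannot be told apart from an effect of the compounds. In both treated groups 14 of 16 members moved opposite to Model against Sham. Over all Model genes 90.5% had the opposite sign in LQ-40 and 96.4% in SQ-3 hearts, so this count gives no support particular to clock genes.

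Interferon response genes were lower in all 3 other groups than in Sham hearts (list medians -2.62 in Model, -2.10 in LQ-40 and -2.36 in SQ-3). More macrophages in the Sham pieces would need most macrophage markers to be lower in Model than in Sham hearts, and 3 of 23 were. Dilution of cardiomyocyte RNA was excluded as the whole cause, since 19 of 20 interferon genes fell further than Tnni3, the contractile gene that fell most (log2 -1.38); the exception was Ddx58 (-1.35). The tables argue against time of day at collection, to the extent that interferon genes would follow the clock list, because the interferon position exceeded the clock position by at least 54.2 points in each treated library, against up to 25.4 in Sham or Model libraries left out of the scale. A response suppressed in the other 3 groups, or one raised in the Sham animals alone by an infection or by housing, may both account for it, and neither was tested.

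The LQ-40 hearts spread widely between Sham and Model, with collagen positions of 34.8, 86.6 and 96.2 and contractile positions of 29.9, 81.6 and 133.7. Scaling was excluded as the cause, since the gap between LQ-40 1 and LQ-40 2 in collagen position was at least 51.5 points with FPKM as deposited and with quantile normalization. An interferon position of 81.8 in LQ-40 1, against -8.4 to 8.7 in Sham libraries, argues against a Sham heart under this label. That holds only if all Sham hearts had the high interferon levels of these 3 libraries, which was not tested. More atrial tissue in LQ-40 1 stays open although 5 other libraries had a higher mean of the atrial list: the bound set before on that count was wrong, since the list had 3 tested members and LQ-40 1 had the highest mean within its group (0.84 against 0.59 and 0.42). A response to the compound that varies between hearts, and the part of the heart that was sampled, also stay open as hypotheses and were not tested.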
